A study of Mus musculus with 8 samples.

How the data were processed

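Only processed data were used: for each array the scanner output file with a signal intensity per spot, and the value table deposited by the authors. Per the file headers, the background-corrected intensity per spot came from Feature Extraction and was on a linear scale. Per the labels, the deposited value table holds a linear ratio to the WT control colon array; in log2 it correlated with the ratio computed from the scanner intensities with r from 0.995 to 0.999 over 18330 features. How the authors scaled their arrays and tested genes was not given in the sources used here. The labels gave the isolation as 8 days in the description of the design and as 16 days in the treatment protocol, and this could not be settled.

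Spots marked as outliers were removed and the rest averaged per probe, which left 40963 of 41174 probes. Probes were named through their transcript accession, which gave 22857 probes for 16309 genes; 18106 probes had no name. The array design refers to an older genome build for which no reference was held, so chromosomes and gene order are given but no coordinates. The log2 intensity of each array was set relative to its 75th percentile. A probe was tested if well above background on at least 4 of 8 arrays (26265 probes, 12716 genes), and in comparisons of 1 array with 1 array if so on at least 1 of them. The probe with the highest mean stood for its gene.

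Tissues were compared through the 4 rectum minus colon differences, 1 per mouse group. Genotype and stress were fitted together to the 4 tissue means, and their dependence on tissue to the 4 differences. The labels do not say that the colon and rectum pools came from the same mice, which the pairing assumed. Tests used limma with a variance trend over the mean level, and a probe was called at an adjusted p (Benjamini-Hochberg) under 0.05. Values after ± are standard errors (SE) from limma, which share variance across probes and can be smaller than the spread of the pairs. For genotype and stress, with 1 residual degree of freedom, they came mostly from the shared variance. Gene lists, 34 in all with 629 of 679 genes on the array, were written before the data were examined and tested with camera at a correlation of 0.01 between genes, then again with an estimated correlation. In comparisons of 1 array with 1 array, list medians were ranked among 10000 random lists of the same size and expression.

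The design, the filters, the lists and the alternatives were chosen before the data were examined, apart from those said to be chosen after. The trend over the mean level of the 8 arrays replaced one over the mean difference after the fit was seen. Genes named in the tested comparisons were the 10 with the largest rise and the 10 with the largest fall among those called, above background on at least 1 array of each side and with the same direction in 4 of 4 pairs. In comparisons of 1 array with 1 array they were the 8 largest in each direction above background on both arrays, and 3 in each direction seen on 1 array alone; some of these are not given here. Il18 and the kallikreins were named beforehand, and further list members were picked as examples after their values were seen.

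Alternatives were quantile normalization, median centring, model-based background correction (normexp, offset 50), the deposited ratios, a common floor, other background filters, tests without the trend, other designs, and leaving out arrays. The mean signal column was not held, so normexp used the median signal and median local background. Spots more than 50 units under their local background were left out there, a choice made after the fit was seen. Testing the 8 arrays without the mouse group as a block gave 7373 calls between tissues where the paired test gave 7219. A block for slide was not run for the tissue comparison or for effects by tissue, since slide and tissue are the same there. Position on the slide went with the mouse group, and these cannot be told apart.

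With simulated changes of 1 and 2 log2 units the tissue test found 43% and 90% of changed probes with 5 false calls among 138. The genotype test found 91% and 100% with 56 false calls among 247, and the stress test 82% and 100% with 28 among 210. In 20 simulated data sets without a change, the genotype test called 0 to 32 probes and the stress test 0 to 21. All simulations drew noise independently for each probe, with variances around the fitted trend. They therefore checked the fit under its own assumptions and not under noise shared across genes. Analyses used R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.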

Results

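Gene expression was measured in the mucosa of the middle colon and of the rectum of male wild-type (WT) mice and of mice without the gene for the cytokine interleukin 18 (IL18ko). Mice were either kept with their brothers (control) or housed alone as a psychological stress. Each of the 8 combinations of tissue, genotype and housing gave 1 array, hybridised with RNA pooled from 5 mice, so no group had a replicate. Between 62.2% and 66.4% of the 43379 spots on an array lay well above background, and no spot was saturated. Across genes, arrays of the same tissue correlated with r from 0.981 to 0.994, and arrays of different tissues with r from 0.944 to 0.960. All log2 values below are relative to the 75th percentile of their array.

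The targeted gene matched the labels on each array. Il18 was at 2.68 on the control and 2.83 on the stress array of WT colon, and at 4.35 and 5.81 in WT rectum. It was not above background on any of the 4 IL18ko arrays, where its values lay between -8.01 and -7.62. The WT level was at least 1210-fold higher over both tissues, at least 519-fold in colon and at least 2822-fold in rectum.

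The first comparison asked how the rectum differs from the middle colon. Among genes above background in both tissues, the largest rise in rectum was that of the sodium pump regulator Fxyd4, by 10.55 ± 0.13 (log2, SE, n = 4 pairs); the epithelial sodium channel subunit Scnn1g rose by 6.07 ± 0.21 and the proton pump Atp12a by 5.70 ± 0.14. The positional gene Hoxd10 rose by 5.80 ± 0.17, and the sulfotransferase Sult1e1, the sugar phosphate exchanger Slc37a2 and the sialyltransferase St8sia5 rose by 6.36, 6.28 and 6.20. The lectin gene Reg3b fell by 10.27 ± 0.79, Retnlb fell by 9.45 ± 0.70, Reg3g fell by 8.15 ± 0.77 and Ang4 fell by 7.56 ± 0.10. Sptssb (-10.53 ± 0.49), Apol10a (-7.92), Plet1 (-7.06), Tmigd1 (-6.97), Nts (-6.63) and Tmem252 (-6.63) fell too. The muscle genes Myh4 (7.54 ± 1.76), Tnnc2 (6.40 ± 0.92) and Mb (5.76 ± 1.22) rose with far larger errors, and the 4 pairs of Myh4 ranged from 1.28 to 13.65. Reg3b was well above background on 2 of the 4 rectum arrays, Reg3g on 1 and Sptssb on 3, and Sult1e1, Myh4 and Mb on 1 and Hoxd10 on 2 of the 4 colon arrays, so that their sizes carry the noise of low signals.

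**Figure D1:**
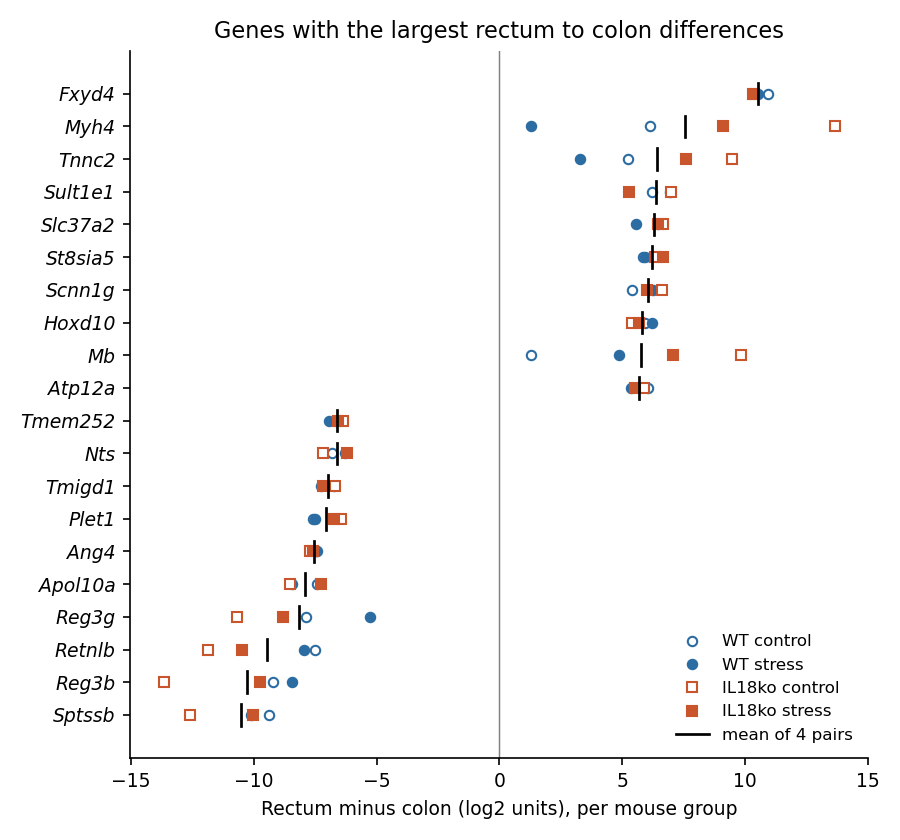
Rectum minus colon difference (log2 units) of the 10 genes with the largest rise and the 10 with the largest fall among called genes above background in both tissues and with 1 direction in 4 of 4 pairs, each point a mouse group (1 colon and 1 rectum array) and each bar the mean of the 4 pairs. Fxyd4 (10.55) and Sptssb (-10.53) lie at the ends, and the pairs of the muscle genes Myh4, Tnnc2 and Mb spread most widely.

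Of the gene lists fixed beforehand, 12 of 33 differed between the tissues. None of these calls held in camera with an estimated correlation, where their adjusted p lay between 0.424 and 0.531. With 3 residual degrees of freedom that test could pass few lists, so it cannot decide on these calls. The estimated correlation lay far above the set 0.01 for skeletal muscle (0.76), adipocytes (0.58), enteric neurons and glia (0.51), macrophages (0.40) and cell cycle (0.19). For the other called lists it was at most 0.08. Enteric neurons and glia were lower in rectum (median -1.35; 0 of 13 genes higher, 12 lower, 1 not passing; 13 passing when adjusted over the list alone), with Elavl4 at -1.93, Uchl1 at -1.78 and Vip at -1.24. The enteroendocrine list was lower (median -1.03; 2 higher, 9 lower, 4 not passing; 12 over the list alone), with Cck at -3.89, Pcsk1 at -2.40 and Sst at -2.32, while Isl1 was higher at 2.42. The goblet cell list was lower (median -0.91; 2 higher, 11 lower, 4 not passing; 13 over the list alone), with Tff2 at least 10.5-fold lower and Muc4 (-2.84) and Spdef (-2.56). The interferon list was lower (median -0.47; 1 higher, 14 lower, 13 not passing; 16 over the list alone), with Cxcl9 at least 3.89-fold lower and Oas2 at -2.48. Heat shock and ER stress genes (median -0.52; 0 higher, 10 lower, 9 not passing; 12 over the list alone) and cell cycle genes (median -0.37; 0 higher, 10 lower, 11 not passing; 10 over the list alone) were lower, with Hsph1 at -1.62 and Ccnb1 at -1.04. Adipocyte genes (median -1.26; 0 higher, 8 lower, 3 not passing; 9 over the list alone), fatty acid oxidation and ketogenesis (median -0.32; 1 higher, 5 lower, 12 not passing; 10 over the list alone) and sterol synthesis (median -0.33; 1 higher, 7 lower, 11 not passing; 10 over the list alone) were lower as well. Among them Fabp1 fell at least 19-fold, Cidec fell by 2.47 and Lss fell by 1.09. Higher in rectum were skeletal muscle (median 4.01; 10 of 16 genes higher, 0 lower, 6 not passing; 14 over the list alone), the circadian clock (median 0.75; 12 higher, 2 lower, 2 not passing; 15 over the list alone) and macrophages and dendritic cells (median 0.78; 8 higher, 0 lower, 9 not passing; 11 over the list alone). Nr1d1 (2.92), Ciart (2.21), Clec10a (2.36) and Cd163 (1.91) were among their members.

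Single genes of lists that were not called also differed. Hoxd13 (at least 126-fold), Hoxd11 (at least 17.9-fold) and Hoxb13 (3.38) rose while Hoxb8 (at least 2.81-fold) and Cdx2 (-3.62) fell, so that 6 posterior Hox genes were higher and 7 lower. The median of that list was 0.12 but its test pointed down, and the median turned to -0.02 with model-based background, -0.21 in the deposited ratios and -0.03 with a common floor. The antimicrobial list had a median of 0.78 and a mean of -1.02, since S100a9 (5.03) and Ltf (at least 18.5-fold) rose against the fall of Reg3b and Retnlb. Cxcl5 (at least 28.7-fold), Alox15 (at least 11.1-fold), Cma1 (5.38) and Klk15 (4.70) rose, and Gzma (-3.46), Jchain (-3.33) and Cyp3a44 (at least 18.5-fold) fell. Klk15 was above background on 1 and Cma1 on 3 of the 4 colon arrays, and Gzma on 1 of the 4 rectum arrays, so that their sizes are not exact. The IL-18 pathway, MHC class II, glucocorticoid, stress peptide and serotonin, kallikrein, cytokine, absorptive colonocyte, stem cell, immediate early, xenobiotic and Il18 neighbour lists did not pass. Nor did squamous epithelium, smooth muscle, B and plasma cells, T and NK cells (adjusted p = 0.0562), neutrophils and eosinophils, mast cells, fibroblasts and endothelium, or male accessory and anal glands.

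The comparison rested on 4 rectum minus colon differences, 1 per mouse group, tested with limma. It called 7219 of 26265 probes, 3681 higher and 3538 lower in rectum, and 7181 of them moved the same way in all 4 pairs; 3031 differed at least 2-fold. Every colon array was on 1 slide and every rectum array on the other, so tissue and slide cannot be told apart. Without the pair of WT control arrays the count was 3505, and without the pair of IL18ko control arrays 3793.

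The genotype comparison asked which genes depend on IL-18 over both tissues and both kinds of housing. Beside Il18 itself, the largest fall among genes above background in both genotypes was in Nxpe4, a gene of the same chromosome 9 region, which fell by 5.71 ± 0.13 (log2, SE, n = 2 IL18ko and 2 WT mouse groups; adjusted p = 5.49e-13). Sbp, of the male accessory and anal gland list and above background on no IL18ko array, fell at least 33.4-fold. Averaged over genotypes, it differed with stress by -1.64 in rectum and 2.20 in colon, so its level varied beyond genotype. The neighbour of Nxpe4, Nxpe2, fell by 1.99 ± 0.13 and Atm, on the other side of Il18, fell by 1.89 ± 0.18. Fmr1nb, of the X chromosome, fell by 3.36 ± 0.27 but was above background on 1 of the 4 IL18ko arrays, so that its size is not exact. Retnlb, a goblet cell defence protein, fell by 2.23 ± 0.16, with pairs from -4.86 to -0.50. Among genes above background in both genotypes and higher in IL18ko mice in 4 of 4 pairs, those that rose most were Lrp8 (2.54 ± 0.21), Lypd3 (2.38 ± 0.23), Lce3f (2.31 ± 0.37), the adipocyte genes Lep (1.95 ± 0.33) and Plin1 (1.71 ± 0.13), Aqp3 (1.87), Car3 (1.82), Ltf (1.74), Txlnb (1.69) and Sln (1.61). Of these 10 genes, limma called 0 with the 8 arrays as independent and Lrp8 alone without the trend of the variance, while Nxpe4, Fmr1nb and Atm were called in both. Nxpe2 was called in the first of these fits alone, and Retnlb in neither. The pairs lay far apart, from 0.08 to 3.96 in Lce3f, from 0.20 to 2.91 in Ltf and from 0.15 to 4.84 in Sln. In the test of tissue dependence the difference, averaged over housing, was larger in rectum than in colon for Car3 (2.72 and 0.92), Ltf (2.87 and 0.60) and Sln (2.50 and 0.73). For Sln this did not hold under both control and stress housing. Lep was above background on 1 of the 4 WT arrays, Lrp8, Lce3f, Aqp3, Ltf and Txlnb on 2 and Lypd3 on 3, so that these sizes are not exact either. The other genes with large falls were Olfr225 (-1.94), 1700001C19Rik (-1.73), Cacng8 (-1.66), Olfr1282 (-1.44) and Trim66 (-1.29). Of these, Cacng8 was above background on all 4 IL18ko arrays, Trim66 on 2 and the others on 1. None of them was called with the 8 arrays as independent or without the trend.

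Where fewer probes were called, many were of chromosome 9, which held 722 of the 12716 tested genes, an observation made after the values were seen. Treating the 8 arrays as independent, without the pairing of tissues by mouse group, left 32 probes (5326 with the mouse group as a random block), 26 of them with a gene name, and 15 of these lay on chromosome 9, from 14 genes with Il18 included. Apoc3, 20 tested genes from Il18 and above background on no WT array, was higher in IL18ko mice at least 6.24-fold with 1 probe and 4.97-fold with the other, and Fxyd6 by 1.20 and 1.09 on the log2 scale. Trappc4 (-0.88 and -1.17) and Pts (-0.57 and -0.77) were lower with both probes. In contrast, Ift46 was at least 7.18-fold lower with 1 probe and at 0.28 with the other, Pcsk7 at -1.96 and 0.01, Rps25 at -1.77 and -0.40, and Anp32a at 1.95 and -0.03. Cadm1 had 3 probes, at 0.60, 0.00 and 1.18, and Cacna2d2 differed by -0.81 with its brighter probe and 0.16 with the other. Of these 14 genes, Cacna2d2 and Anp32a lay more than 50 tested genes from Il18. By size alone, 12 of its 722 genes (11 of 721 without Il18) differed at least 2-fold on average and in the same direction in 4 of 4 pairs. On chromosome 6 this held for 11 of 643, and every other chromosome had a smaller share. Beyond the 100 tested genes nearest Il18, it held for 85 of 12615 genes (0.67%).

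**Figure D2:**
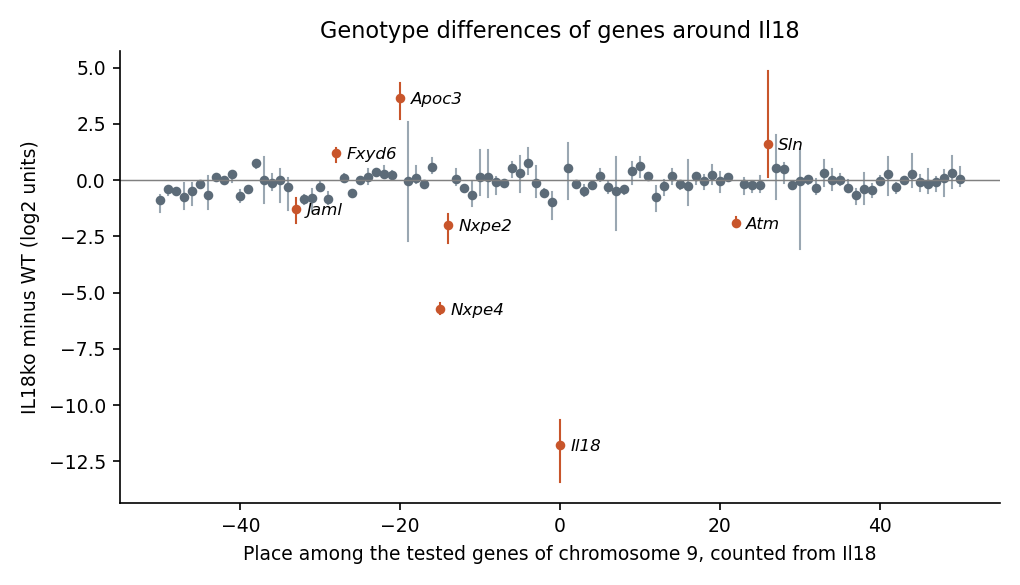
IL18ko minus WT difference (log2 units) of Il18 and the 50 tested genes on either side of it on chromosome 9, in chromosome order; points are the means and lines span the 4 pairs of arrays. Coloured genes differed at least 2-fold on average and in the same direction in 4 of 4 pairs, among them Nxpe4 (-5.71) and Apoc3 (3.64, above background in IL18ko mice alone).

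By gene list, 13 of 33 differed between the genotypes. None of these calls held in camera with an estimated correlation (adjusted p = 0.564 for 12 of them and 0.641 for squamous epithelium). With 1 residual degree of freedom that test could pass hardly any list, so it cannot decide on these calls. The estimated correlation was 1 for skeletal muscle, smooth muscle and enteric neurons and glia, far above the 0.01 first set. It was 0.38 for squamous epithelium and 0.24 for cell cycle, and at most 0.05 for the other called lists. For adipocytes the estimated correlation was -0.02, below the 0.01 first set, yet the unadjusted camera p went from 1.82e-13 to 0.0819. The gene counts below come from the fit with 3068 calls, which fell to 18 without the trend and 32 with the 8 arrays as independent. Neither of those fits called a gene of the adipocyte, smooth muscle, fibroblast and endothelium, cell cycle or MHC class II lists. Myh2 was called in both, Klf4 and Cdx2 with the 8 arrays as independent, and Sbp without the trend. Adipocytes had the largest median (1.28; 9 of 11 genes higher, 0 lower, 2 not passing; 9 over the list alone), with Adipoq at 1.41 and Cfd at 1.35, followed by skeletal muscle (median 1.14; 8 higher, 0 lower, 8 not passing; 11 over the list alone), with Ryr1 at 1.55. Adipoq differed by 2.43 in rectum and by 0.38 in colon. The skeletal muscle difference rested on the IL18ko control rectum array, where the list was at a level of 2.71, against -1.63 in WT control rectum. Under stress the levels were 0.38 in IL18ko and -0.10 in WT rectum, and -3.55 in IL18ko and -1.64 in WT colon. In colon, Tnni2 and Tnnc2 had mean genotype differences of -1.46 and -1.32. Smooth muscle (median 0.54; 7 higher, 0 lower, 5 not passing; 10 over the list alone), fibroblasts and endothelium (median 0.36; 7 higher, 0 lower, 9 not passing; 13 over the list alone) and enteric neurons and glia (median 0.35; 3 higher, 0 lower, 10 not passing; 5 over the list alone) were higher, with Des at 0.66, Acta2 at 0.60 and Tie1 at 0.82. Immediate early genes (median 0.21; 4 higher, 0 lower, 11 not passing; 4 over the list alone) included Klf4 (1.34) and Egr1 (0.74). The glucocorticoid list (median 0.22; 2 higher, 1 lower, 16 not passing; 3 over the list alone), the posterior Hox list (median 0.18; 3 higher, 0 lower, 15 not passing; 4 over the list alone) and squamous epithelium (median 0.19; 4 higher, 0 lower, 13 not passing; 4 over the list alone) were higher, with Pdk4 at 1.04, Krt5 at 2.23 and Col17a1 at 1.29. Krt5 differed by 4.05 in rectum and by 0.41 in colon. Cell cycle genes were lower (median -0.32; 0 of 21 higher, 9 lower, 12 not passing; 16 over the list alone), with Rrm2 at -0.62 and Pcna at -0.43. The antimicrobial list (median -0.31; 1 higher, 7 lower, 11 not passing; 10 over the list alone) held Itln1 at -1.13 and Ang4 at -0.61. MHC class II (median -0.25; 0 higher, 3 lower, 6 not passing; 3 over the list alone) held H2-DMb1 at -0.59 and H2-Ab1 at -0.53, and the male accessory and anal gland list was lower (median -0.39; 0 higher, 2 lower, 4 not passing; 2 over the list alone).

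Among lists that were not called, the cytokine list had 2 genes higher and 6 lower, with Ccl4 at -1.20 and Tnf at -0.79, and the IL-18 pathway had Il1b at -1.15 and Pycard at -0.44. The Il18 neighbour list had 4 higher and 7 lower of 30, Bco2 (-0.97) and Ncam1 (0.75) among them. The interferon, stress peptide and serotonin, kallikrein, goblet cell, absorptive colonocyte, enteroendocrine, stem cell, circadian, heat shock, fatty acid, sterol and xenobiotic lists did not pass. The lists for B and plasma cells, T and NK cells, macrophages and dendritic cells, neutrophils and eosinophils, and mast cells did not pass either.

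The genotype test called 3068 of 26265 probes, 1614 higher and 1454 lower, from 4 tissue means with 1 residual degree of freedom; 2358 moved the same way in 4 of 4 pairs and 262 differed at least 2-fold. With arrays centred on their median the balance turned to 777 higher and 1365 lower. The count was 18 without the trend of the variance along the expression level. It was 32 with the 8 arrays as independent. Arrays were left out in that design, so those counts stand against 32 and not 3068. They ran from 6 (without IL18ko control rectum) to 23, except that leaving out WT stress rectum gave 3597.

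Stress was compared with control housing over both tissues and genotypes. The vitamin D dependent calcium-binding gene S100g fell by 1.45 ± 0.11 (log2, SE, n = 2 stressed and 2 control mouse groups; adjusted p = 5.73e-05), with pairs from -2.52 to -0.42. The gut peptide gene Nts fell by 0.79 ± 0.13 and the adipocyte hormone Adipoq fell by 0.72 ± 0.12. The transcription factor Tfap2e rose by 1.02 ± 0.12, Rusc1 by 0.69, the clock output gene Dbp by 0.68 ± 0.11, Foxq1 by 0.68 and the glutamate receptor subunit Grin2d by 0.64. Each moved in the same direction in 4 of 4 pairs, which the choice of named genes required, and the other probe of Rusc1 differed by 0.11. Il18 did not pass in limma (0.53 ± 0.15, adjusted p = 0.270). Its mean includes the IL18ko arrays, where it had no signal above background, so this does not test a stress effect on Il18.

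Of the 33 lists, 5 differed with stress, and none in camera with an estimated correlation (adjusted p = 0.978 for each). As for genotype, that test had 1 residual degree of freedom and cannot decide on these calls. Immediate early genes were higher (median 0.28), as were macrophages and dendritic cells (median 0.22) and fibroblasts and endothelium (median 0.20), while adipocytes (median -0.19) and heat shock and ER stress genes (median -0.09) were lower. The macrophage and fibroblast lists averaged opposite movements. In rectum their medians were 0.63 and 0.62 in WT mice but -0.29 each in IL18ko mice. Over all genes 0 immediate early genes passed in limma (15 not passing; 4 over the list alone), 0 of 17 macrophage genes (3 over the list alone), 0 of 16 fibroblast and endothelial genes (1 over the list alone), and 0 of 19 heat shock genes (1 over the list alone); Adipoq was the adipocyte gene that passed, with 10 not passing (3 over the list alone). Dbp and Nts were the members of the circadian and enteroendocrine lists that passed. The glucocorticoid list (median 0.05; 0 over the list alone) and the stress peptide and serotonin list (median 0.07; 0 over the list alone) did not pass. The other 24 lists, kallikreins, cytokines and the IL-18 pathway among them, did not pass in the test of lists.

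Across 11795 genes, 23 differed by at least 0.3 in 1 direction in all 4 pairs. More, 115, did so with WT colon and IL18ko rectum in 1 direction and IL18ko colon and WT rectum in the other.

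The stress test called 23 of 26265 probes, 17 higher and 6 lower, and 2533 had an unadjusted p under 0.05. Simulated data without any change gave 0 to 21 calls in 20 draws. Their noise was independent between probes, with variances drawn around the fitted trend. Noise shared across genes was not simulated, so these draws do not show how many of the 23 calls to expect without a change. Treating the 8 arrays as independent gave 0 calls. Leaving out any 1 array in that design also gave 0, which does not show what 1 array adds to the 23. Controls were killed before and stressed mice after the isolation period, so age and day went with stress.

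Within single tissues and genotypes each difference compared 1 array with 1 array and has no replicate check, so what follows are values without a test. A list is described as standing apart when its median lay outside the central 95% of 10000 random lists matched on expression.

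In WT rectum, skeletal muscle genes were far higher on the stress array: Mb by 4.69, Myh1 by 4.57, Myl3 by 4.08, Tnni2 by 3.23, Myl1 by 3.18, Myoz1 by 3.08 and Myh8 by 2.79. The vesicular glutamate transporter Slc17a8 was higher by 3.24 and Il18 by 1.46. Gria4 (at least 17-fold), Rhox6 (at least 14.1-fold) and Tmem215 (at least 11.6-fold) were seen on the stress array alone. Lower were the secretory gland genes Tgm4 (-4.95) and Sbp (-3.05), the integrin Itgam (-3.68), and Apba2 (-2.69), Olfr24 (-2.57), Kcnn1 (-2.51), Olfr734 (-2.38) and Wdr17 (-2.35). Pbsn (at least 15.2-fold), Gm4861 (at least 11.8-fold) and the bradykinin receptor Bdkrb2 (at least 11.4-fold) were lost from the stress array. The skeletal muscle list (median 2.37, 12 of 16 genes at least 2-fold higher, percentile 100) stood apart, as did macrophages (0.63), fibroblasts and endothelium (0.62), immediate early genes (0.48), B and plasma cells (0.38) and cell cycle (0.36). Adgre1 (1.32), Col1a1 (1.31), Junb (1.25) and Fos (1.14) were among their members. Smooth muscle (-0.62, percentile 0), enteric neurons and glia (-0.39), goblet cells (-0.29), sterol synthesis (-0.24) and absorptive colonocytes (-0.045) stood apart on the low side, with Myh11 at -1.33, Des at -1.25, Prph at -1.69 and Cyp51 at -1.23. Male accessory and anal glands were low too (-0.89), but at 0.03 with model-based background. At least 2-fold differences were seen in 2043 probes, 1088 higher and 955 lower, of which 1175 were well above background on both arrays (676 higher, 499 lower). The balance turned with the processing, to 189 higher and 546 lower in the deposited ratios and 247 and 108 with model-based background.

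In IL18ko rectum the same muscle genes were lower on the stress array. Myh4 was at -3.57, Mlf1 at -2.85, Ttn at -2.79 and Mb and Myh8 at -2.62 each, and the skeletal muscle list had a median of -2.15 with 14 of 16 genes at least 2-fold lower. Gland genes were lower as well: 2310057J18Rik (-12.36), Mup4 (-4.38), Prol1 (at least 338-fold), Pip (at least 190-fold) and Wfdc15b (at least 59.6-fold), along with Derl3 (-2.94), Hpca (-2.87) and Elf5 (-2.74). Higher were Cd5l (2.27), Septin3 (2.11), Ccdc14 (2.11), Olfr578 (2.03), Myh7 (1.94), Hbb-bh1 (1.90), Mospd3 (1.78) and Calm4 (1.56), and Piwil1, Apoa5 and Nlrp4a were seen on the stress array alone (at least 14.1-fold, 11.7-fold and 11.2-fold). Squamous epithelium and skin stood apart on the high side (0.45, percentile 100), with Krt6b at 1.39 and Krt4 at 1.17, as did kallikreins (0.20), enteric neurons and glia (0.19), sterol synthesis (0.18), posterior Hox genes (0.15), immediate early genes (0.09) and absorptive colonocytes (0.027). Low were male accessory and anal glands (-0.56), neutrophils and eosinophils (-0.55), adipocytes (-0.44), fibroblasts and endothelium (-0.29), macrophages (-0.29), B and plasma cells (-0.21), heat shock (-0.18) and cell cycle (-0.12; 0.01 in the deposited ratios). S100a8 (-1.76) and Lep (-1.25) were the lowest of the neutrophil and adipocyte genes. There were 848 probes at 2-fold or more, 389 higher and 459 lower, and 273 of them were well above background on both arrays (70 higher, 203 lower). Model-based background gave 16 higher and 94 lower, the deposited ratios 14 and 43, and a common floor 146 and 279.

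In WT colon the stress array was again higher in muscle genes, with Tnnc2 at 4.17, Myh8 at 3.99 and Myh4 at least 63.2-fold higher, and in Sbp (4.28). Prl8a8 (3.33), Cacng8 (3.05), Slc35g3 (2.68) and Mgat5b (2.53) were higher, and Olfr1411 and Hoxc9 were seen on the stress array alone (at least 18.3-fold and 16.1-fold). The defence lectin Reg3b was lower (-3.56), with Acsbg1 (-3.67), 1700001C19Rik (-3.31), Plagl1 (-3.10), Col4a5 (-3.10), Ifna1 (-3.06), Rragb (-2.81) and Cyp3a44 (-2.77), and Klk15, Onecut1 and Olfr1364 were lost (at least 23.6-fold, 23.5-fold and 19-fold). Il18 differed by 0.15. Skeletal muscle (1.03), glucocorticoid genes (0.10) and absorptive colonocytes (0.088) stood apart on the high side, with Per1 at 0.59. On the low side were adipocytes (-0.69), cytokines (-0.40), B and plasma cells (-0.32), T and NK cells (-0.21), fibroblasts and endothelium (-0.20), smooth muscle (-0.18), cell cycle (-0.14) and heat shock (-0.10), with Retn at -1.44, Ccl2 at -0.89 and Gzma at -1.22. At least 2-fold differences were seen in 1237 probes, 584 higher and 653 lower, and 317 were well above background on both arrays (114 higher, 203 lower).

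In IL18ko colon the stress array was higher in genes of immune and stromal cells. B and plasma cells (0.80, percentile 100), macrophages (0.71), fibroblasts and endothelium (0.67), cytokines (0.59), immediate early genes (0.45), smooth muscle (0.41), MHC class II (0.33), skeletal muscle (0.28) and sterol synthesis (0.17) stood apart. Pou2af1 (1.20), Col3a1 (0.97), Cxcl12 (1.07) and Egr2 (1.28) were among their members. T and NK cells (-0.17), interferon genes (-0.14), heat shock (-0.14) and cell cycle (-0.09) stood apart on the low side, with Gzmb at -1.35 and Irf7 at -0.69. The largest single differences were Pcdhb3 (3.09), Mdfi (3.08), Olfr570 (2.82), Lce3f (2.55), Hapln4 (2.38), the tachykinin Tac2 (2.17), Igsf11 (1.78) and Abra (1.75) on the high side. Il21r (-3.34), Gprc5d (-3.12), Wdr54 (-2.75), the cannabinoid receptor Cnr2 (-2.43), S100g (-2.20), Osr2 (-2.0), Kcnj12 (-1.80) and Syt16 (-1.69) were lowest. Cts3, Elfn1 and Olfr690 were seen on the stress array alone (at least 12.4-fold, 11.6-fold and 5.20-fold), and Olfr171 and Olfr800 on the control array alone (at least 14.7-fold and 11.8-fold). There were 1037 probes at 2-fold or more, 593 higher and 444 lower, 313 of them well above background on both arrays.

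Kallikreins and their receptors showed few large stress differences. Beside Bdkrb2 in WT rectum and Klk15 in WT colon, both lower, Klk7 and Klk14 were seen in IL18ko colon on the stress array alone. Every other kallikrein difference of 2-fold or more came from arrays without signal above background.

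**Figure D3:**
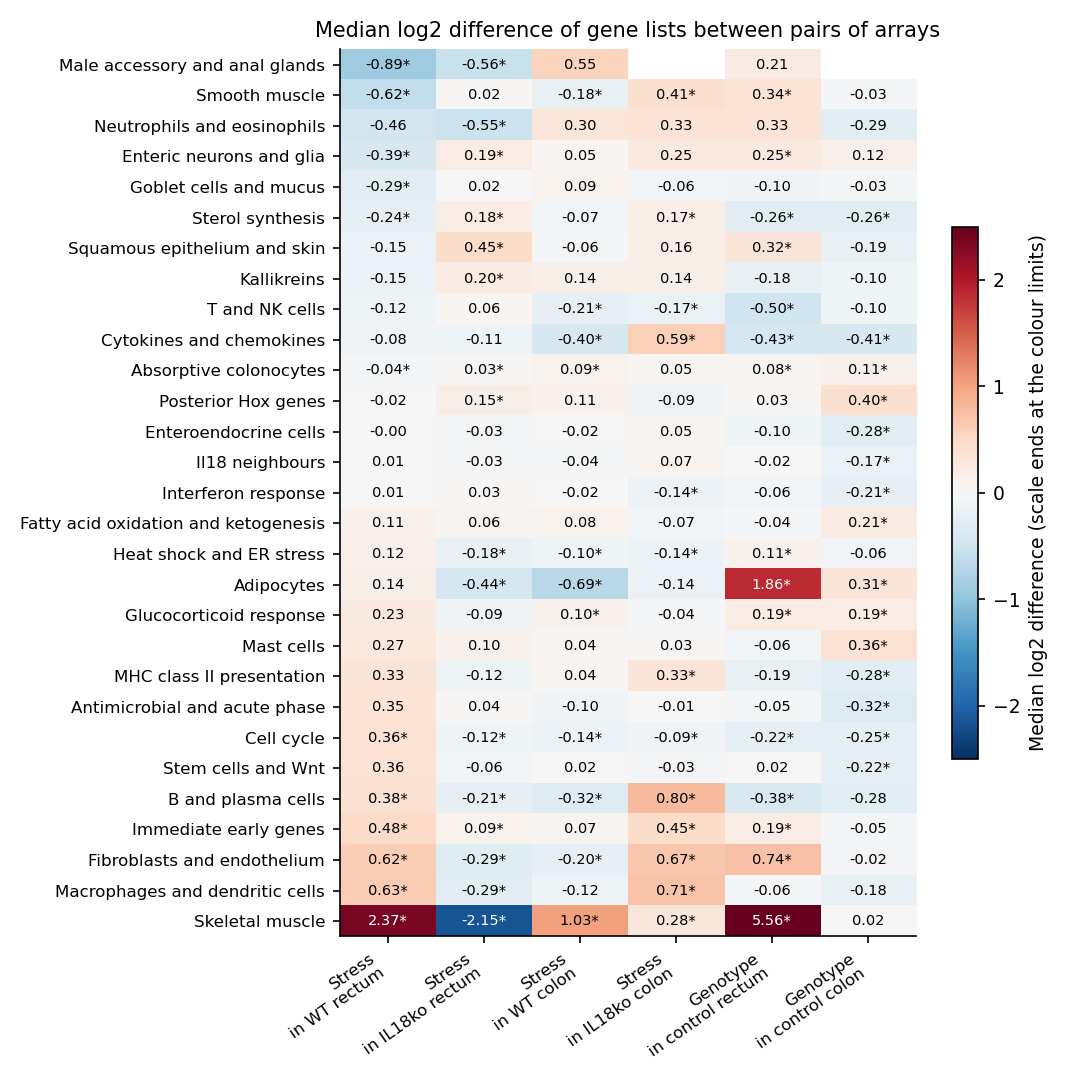
Median log2 difference of gene lists in the 6 comparisons of 1 array with 1 array; a star marks a median outside the central 95% of 10000 random lists, and a blank a list with under 5 measured genes. The skeletal muscle list runs from -2.15 (stress in IL18ko rectum) to 5.56 (genotype in control rectum).

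Between genotypes under control housing, the IL18ko rectum array held far more skeletal muscle transcripts, while gland genes differed in either direction. Mb was higher by 7.72, Myh1 by 7.46, Myh4 by 6.90, Myl3 by 6.53, Myh8 by 6.53, Myoz1 by 6.48 and Actn3 by 6.22, with 2310057J18Rik at 9.62. Prol1 (at least 234-fold), Pip (at least 132-fold) and Myot (at least 41.7-fold) were seen on the IL18ko array alone. Lower in IL18ko rectum were Tgm4 (-5.85), Nxpe4 (-5.45), Retnlb (-4.86), Itgam (-3.63), Bdkrb2 (-3.25), Olfr24 (-2.99), Apba2 (-2.58) and Il1b (-2.35). Il18, Sbp and Pbsn were lost (at least 1573-fold, 45.0-fold and 18.0-fold). Tgm4, Itgam, Bdkrb2, Olfr24, Apba2, Sbp and Pbsn were also lower with stress in WT rectum, against the same WT control array. Skeletal muscle (5.56), adipocytes (1.86), fibroblasts and endothelium (0.74), smooth muscle (0.34), squamous epithelium (0.32), enteric neurons and glia (0.25), immediate early genes (0.19), glucocorticoid genes (0.19), heat shock (0.11) and absorptive colonocytes (0.08; -0.00065 with arrays centred on their median) stood apart on the high side. Adipoq (2.40), Krt5 (3.37) and Klf4 (1.51) were among their members. T and NK cells (-0.50), cytokines (-0.43), B and plasma cells (-0.38), sterol synthesis (-0.26) and cell cycle (-0.22) were low, with Cxcl1 at -1.97 and Cd3e at -0.96. At 2-fold or more were 1791 probes, 1241 higher and 550 lower; 761 were well above background on both arrays.

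**Figure D4:**
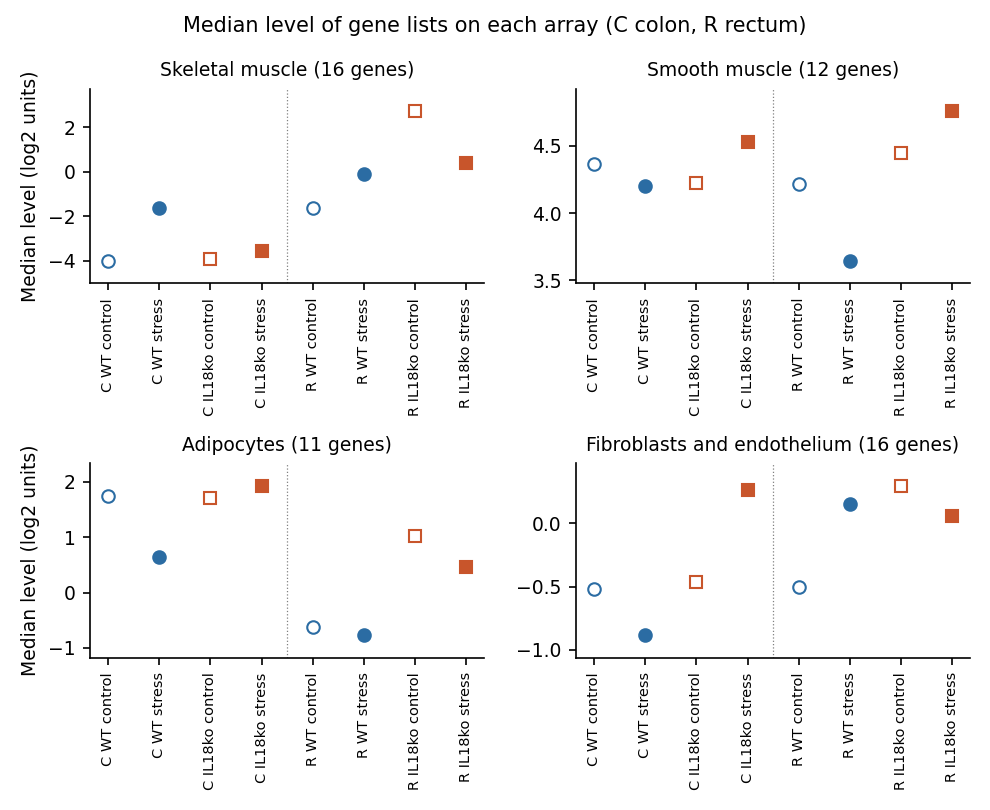
Median level (log2 units relative to the 75th percentile of the array) of 4 gene lists on each array; circles are WT, squares IL18ko, open symbols control and filled symbols stress. Skeletal muscle was highest on the IL18ko control rectum array (2.71) and adipocytes lowest on the WT rectum arrays (-0.63 and -0.77).

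In control colon the genotypes differed less in muscle (median 0.02, not apart). Nxpe4 was lower by a similar amount (-5.76), with Mc4r (-3.78), 1700001C19Rik (-3.75), Myh1 (-3.18), Rragb (-3.12), Acsbg1 (-3.04), Lce1l (-2.54) and Treml4 (-2.44). Il18, Klk15 and Onecut1 were lost (at least 514-fold, 21.2-fold and 21.0-fold). 1700001C19Rik, Rragb, Acsbg1, Klk15 and Onecut1 were also lower with stress in WT colon, against the same WT control array. Tdrd6 (3.35), Gprc5d (2.89), Lrp8 (2.86), Il21r (2.60), Olfr171 (2.50), Wdr54 (2.29), Cnr2 (2.27) and Lypd3 (2.17) were higher. Aipl1 and Olfr26 were seen on the IL18ko array alone (at least 12.0-fold and 10.5-fold). Gprc5d, Il21r, Olfr171, Wdr54 and Cnr2 were also those lower with stress in IL18ko colon, where the same IL18ko control array was subtracted. Posterior Hox genes (0.40), mast cells (0.36), adipocytes (0.31), fatty acid oxidation (0.21), glucocorticoid genes (0.19) and absorptive colonocytes (0.11) stood apart on the high side, with Cdx2 at 1.21 and Angptl4 at 1.07. Cytokines (-0.41), antimicrobial genes (-0.32), enteroendocrine cells (-0.28), MHC class II (-0.28), sterol synthesis (-0.26), cell cycle (-0.25), stem cells (-0.22), interferon genes (-0.21) and Il18 neighbours (-0.17) were low, with Ccl7 at -1.47, Itln1 at -1.24 and Dixdc1 at -2.23. At 2-fold or more were 1292 probes, 515 higher and 777 lower, and 376 were well above background on both arrays. The blood list was measured in the rectum comparisons and stood apart in none of them.

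Whether the effects differed between the tissues was tested directly. The genotype difference depended on tissue for 111 probes, 89 of them more positive and 22 more negative in rectum (73 and 68 with model-based background), with the largest sizes in muscle genes. Myh4 differed between genotypes by 3.82 in rectum and -3.86 in colon, Myh1 by 4.17 and -1.57, and Mb by 4.07 and -1.30, while Retnlb differed by -3.94 and -0.52 (genes chosen after their values were seen). These are means over control and stress housing, and the rectum differences of the muscle genes were far larger under control housing. Myh4 and Mb were each above background on 1 of the 4 colon arrays, so their colon values are not exact. The stress difference depended on tissue for 50 probes, 18 more positive and 32 more negative in rectum (22 and 20 with model-based background). Reg3b differed with stress by -0.05 in rectum and -2.40 in colon, S100g by -0.55 and -2.36, Myh4 by -0.50 and 4.19 and Tgm4 by -2.77 and 0.26 (also chosen after their values were seen), with Reg3b above background on 2 of the 4 rectum arrays. These are means over the genotypes. In rectum Myh4 was higher with stress in WT and lower in IL18ko mice, as was the skeletal muscle list (medians 2.37 and -2.15). Tgm4 fell there mainly in WT mice. Both tests used limma on 4 differences with 1 residual degree of freedom. In both, the variance of a probe was taken wholly from the trend over the mean level, so its own spread did not enter. Myh4 had an SE of 0.48 for genotype by tissue, though its 4 rectum minus colon differences ran from 1.28 to 13.65.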

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

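The tests of skeletal muscle, of scaling, of sequence variants and of level were set out before their results were seen; the tests of genes carried along, of the share of epithelium and of the degrees of freedom were chosen after the result was seen. No group held more than 1 array, so no array was tested as an outlier within its group.

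The stress difference ran in opposite directions in WT and IL18ko rectum for 8 gene lists, none of them tested. The medians in WT and IL18ko rectum were 2.37 and -2.15 for skeletal muscle, 0.63 and -0.29 for macrophages and dendritic cells, 0.62 and -0.29 for fibroblasts and endothelium, and 0.38 and -0.21 for B and plasma cells. They were 0.36 and -0.12 for cell cycle, -0.39 and 0.19 for enteric neurons and glia, -0.24 and 0.18 for sterol synthesis, and -0.045 and 0.027 for absorptive colonocytes. In colon, WT and IL18ko medians were opposite for cytokines (-0.40 and 0.59), B and plasma cells (-0.32 and 0.80), smooth muscle (-0.18 and 0.41) and fibroblasts and endothelium (-0.20 and 0.67). Within a genotype, rectum and colon were opposite too: in WT colon absorptive colonocytes were at 0.088 and cell cycle at -0.14, and in IL18ko colon skeletal muscle was at 0.28 and macrophages and dendritic cells at 0.71. The test by tissue called 50 probes for stress and 111 for genotype, with the variance of each probe taken wholly from the trend over the mean level.

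Skeletal muscle genes differed on the rectum arrays far more than any other list. Muscle taken along with some of the rectum pools may explain this, since the rectum samples came from the 7 mm next to the anus. Among 21 further muscle genes the smaller of the median WT rise and the median IL18ko fall was 0.77. This was short of the 1 log2 unit set beforehand, so by that rule the explanation was left open. The 0.77 was the WT rise, with 13 of the 21 genes higher. The IL18ko stress difference had a median of -1.69, with 18 of the 21 lower. Between genotypes in control rectum, IL18ko minus WT, the median of these genes was 3.25. Scaling of the arrays did not account for it, as the list's smallest median stress difference over the other scalings was 1.67.

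Genotype differences gathered near Il18. Genes carried along with the targeted locus from the strain in which it was made might give them, which was left open because the test restates what prompted it: 7 of the 100 tested genes nearest Il18 differed at least 2-fold on average and in the same direction in 4 of 4 pairs, against 85 of 12615 others (Fisher's exact p = 7.64e-06), among them the muscle gene Sln with pairs from 0.15 to 4.84. Over whole chromosomes, 12 of 722 genes of chromosome 9, Il18 included, and 11 of 643 of chromosome 6 differed so, and every other chromosome had a smaller share. Sequence variants under single probes could also give such differences; over 2 of these genes with a second probe the median ratio of its difference to that of the named probe was 0.98, too few to decide. Further probes within 50 tested genes of Il18 went both ways: they disagreed in Pcsk7 (-1.96 and 0.01), Rps25 (-1.77 and -0.40) and Ift46, and moved together in Trappc4 (-0.88 and -1.17) and Pts (-0.57 and -0.77).

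Across 11795 genes, the stress differences of WT and IL18ko rectum ran against each other. Array differences that depend on the level did not account for it, as the correlation was -0.41 after a trend on the level was removed. A lower share of epithelium in the stressed WT rectum, with the other tissue unchanged in make-up, would move fibroblast and smooth muscle genes together, but their medians lay 1.24 apart. The test was chosen after these medians were seen, and it cannot exclude other changes in the make-up of the sample. Whether the IL-18 genotype might be the source was left open, with 0 residual degrees of freedom for genotype by stress within the rectum.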

How the results depend on the processing

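The design without 2 rectum arrays, WT stress and IL18ko control, picked because they stood apart, was chosen after the result was seen; the other alternatives were chosen before. Of 123 recomputed counts, 53 stayed within 1.5 times of the reported count and 70 moved further.

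For genotype (3068 probes), removing the trend gave 18, treating the 8 arrays as independent 32, slide as a block 32, the mouse group as a random block 5326, rectum alone 319, colon alone 51, and 2 rectum arrays left out 32. The 32 with slide as a block was the same fit as with the 8 arrays as independent. Arrays were left out with the rest treated as independent, where all 8 gave 32. Leaving out 1 array gave from 6 (without IL18ko control rectum) to 3597 (without WT stress rectum).

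For stress (23 probes), quantile normalization gave 4, median centring 3, normexp 224, the deposited ratios 180, a common floor 6, the filter of at least 1 array 77 (40 higher, 37 lower), the filter of all 8 arrays 96 (52 higher, 44 lower), rectum alone 44 (13 higher, 31 lower, 0 shared with the 23) and colon alone 2. In limma without the trend the count was 0 (1862 at unadjusted p under 0.05), with the 8 arrays as independent 0 (893), with slide as a block 0 (893), with a random block 0 (3816), with 2 rectum arrays left out 0 (1014), and without any 1 array 0. The slide block was again the same fit as with the 8 arrays as independent. Arrays were left out with the rest treated as independent, which gave 0 with all 8 arrays as well. Leaving out these 2 rectum arrays turned Il18 from 0.53 to -0.22. Both values include IL18ko arrays without Il18 signal above background, so the turn says nothing on stress.

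Between tissues (7219 probes), leaving out 1 mouse group gave from 3505 (without WT control) to 10737 (without WT stress). For stress by tissue (50), the deposited ratios gave 8, the filter of all 8 arrays 11 and no trend 93; for genotype by tissue (111) these were 30, 46 and 199. List calls with an estimated correlation were 0 for tissue (12 before), 0 for genotype (13) and 0 for stress (5). With 3, 1 and 1 residual degrees of freedom these tests could pass few lists if any. The calls therefore rest on the set correlation of 0.01, unchecked. For several tissue and genotype lists the estimated correlation lay far above it.

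Differences of at least 2-fold in comparisons of 1 array with 1 array fell in number with normexp, the deposited ratios, a common floor, and both arrays above background. Stress in WT rectum gave 355, 735 and 1175 with normexp, the deposited ratios and both arrays. With the common floor put between the deposited ratios and both arrays, stress in IL18ko rectum gave 110, 57, 425 and 273, in WT colon 177, 73, 627 and 317, and in IL18ko colon 103, 80, 513 and 313. Genotype gave 274, 239, 1186 and 761 in control rectum and 183, 95, 696 and 376 in control colon.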

Other observations

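The splits of the mouse groups were chosen after the result was seen, and the sign flips and the splits of 8 arrays before.

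Flipping the signs of the 4 tissue differences gives 8 splits, too few for a share under 0.05; the real one gave 7219 calls and the highest other 0, so that 1 of the splits reached the real count. Without the pairing, 1 of 35 splits of the 8 arrays reached the real count of 7373, and the highest other gave 10. The 4 mouse groups can be split 3 ways, too few for a share under 0.05: genotype gave 83 calls and the highest other 0, with 1 split at or above the real count. Stress gave 0 calls and the highest other, the genotype split, 83, with 3 splits at or above the real count.

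The genotype count also depended on what was left in the residual: it was 3068 with stress fitted, 1708 with genotype by stress fitted instead of stress, and 83 with neither. The stress count fell from 23 with genotype fitted to 0 in limma with genotype by stress fitted instead, and the split by genotype and stress together gave 52 calls with genotype fitted and 2 with stress fitted.

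Stress differences in WT rectum correlated at 0.37 with those in IL18ko colon, and those in IL18ko rectum at 0.32 with those in WT colon, across 11795 genes. The other pairs ran the other way. WT and IL18ko differences correlated at -0.41 in rectum and -0.09 in colon. Rectum and colon differences correlated at -0.16 in WT and -0.14 in IL18ko mice.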
